A study of Mus musculus with 3 samples.

How the data were processed

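DNA copy number was measured by comparative genomic hybridization on 3 dual-colour Agilent mouse arrays of 1 design. On each array the polyploid sample was labelled with Cy5 and the diploid sample with Cy3, so a positive log2 ratio means a larger share of a segment in polyploid cells. Per the file headers, the arrays were read with Agilent Feature Extraction 10.1.1.1. The deposited signals are in units of intensity after background subtraction, spatial and multiplicative detrending, replacement of dim signals by surrogate values and linear dye normalization. The deposited ratios are log10 values of the red over the green processed signal, and the deposited value table held the same numbers. The authors also deposited normalized and smoothed log2 ratios per probe, whose normalization and smoothing window are not given in the sources used here. The deposited probe GC content is in percent. The deposited number of genomic matches of a probe is a score and was not used. The genome build was not given in the sources used here, and positions are those of the array files. The last probe of chromosome 1 starts at 197158929, beyond the last gene end of 195291439 on that chromosome in the GRCm38.p6 gene table, so genes were matched by name and not by position.

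Each array held 967261 probe spots for 963261 probes. Spots marked as non-uniform or as population outliers by the scanner software were removed (628, 155 and 362 spots on TGC replicate 1, TGC replicate 2 and MK), ratios were computed as log2 of red over green processed signal, spots were averaged per probe, and each array was centred on the median of its autosomal probes. No loess or quantile step was applied, since many probes may shift one way. Probes were averaged over fixed bins of 100 kb with at least 10 probes and over genes with at least 5 probes. Of 30207 gene names on the arrays, 15278 matched a current symbol, 2289 matched by accession and 78 by synonym, and 12562 kept the name of the array. Arrays are centred, so a ratio shows unequal shares within 1 array and gives no absolute copy number.

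TGC replicates 1 and 2 formed 1 group and the MK array the other. The TGC mean was tested against 0 with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with a prior variance trended on the log2 number of probes. The prior had infinite degrees of freedom, so the error of each bin or gene is set by its probe number and not by its own 2 values. Bins and genes were called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 ratio of at least 0.2. Domains were runs of at least 2 called bins of 1 direction, joined across a gap of at most 1 bin. The 1 MK array allowed no test, so regions of at least 3 adjacent bins with an absolute ratio of at least 0.2 were counted by size alone, on each TGC array too. TGC minus MK was fitted by limma with a group term, which assumes that the lone MK array varies like the TGC arrays. Correlations between arrays over autosomal bins were compared with 10000 circular shifts along the autosomes, two-sided. With 2 arrays an exact test of 1 value cannot reach a p of 0.05, so chromosome medians were given without one.

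Gene lists were prolactins, placental cathepsins, Psg and Ceacam genes, Serpinb genes, the NK receptor complex, the histone cluster, trophoblast, megakaryocyte and endocycle genes, very long neuronal and adhesion genes, cadherins and protocadherins, olfactory and vomeronasal receptors, ribosomal proteins, proteasome subunits, and the immunoglobulin and T cell receptor loci. They were tested in TGCs with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists), beside an estimated correlation, for lists with at least 3 measured members. With 2 arrays the test with an estimated correlation has 1 residual degree of freedom, so it can hardly call a list and its p decides little. Each list's median was also ranked among 10000 random lists of the same size matched on number of probes. Those lists were drawn over the whole genome, so neither this rank nor the preset correlation allows in full for neighbouring genes with a shared value. On the MK array only this rank was given. Clusters were ranked as regions among windows of the same length. Lists, tests, thresholds and the rule for named items were chosen before the data were examined. That rule took, in each direction, the 10 called TGC domains with the largest absolute mean (up to 3 genes each), the 10 called genes with the largest absolute mean and the same sign on both arrays (at most 2 per 1 Mb), and the 5 largest MK regions. It also took, of each list, its 4 members with the largest absolute mean and its called members.

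The calling of bins and domains was tested on simulated data with the noise of the 2 TGC arrays shuffled among bins of like probe number, a form of noise chosen after a first trial had mixed sparse and dense bins. With 200 planted bins, 80% of those at -0.3 and 80% of those at 0.3 were called, 100% at -0.5 and 98% at 0.5. Of all calls 5.29% (10 bins) fell on unchanged bins, and 58 planted domains of 8 bins at -0.3 were all found with 0 domains called elsewhere. Shorter domains, such as most of those called, were not planted. The shuffle also broke any likeness of neighbouring bins, so the 0 false domains were nearly bound to follow and say little about the real arrays. Alternatives covered bin size, median of probes, minimum probe number, background correction, loess, centring, filters on dim probes, GC content, size thresholds, the variance trend, the authors' own values, run length and leaving out 1 TGC array, which leaves a size rule and no test. Chosen after the data were seen were a GC fit on bins, filters on probes bright on the TGC arrays or on the MK array, the MK sign (for regions, lists and TGC minus MK), autosomal genes only and the repeats of the MK list ranks. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3.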

Results

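Trophoblast giant cells (TGCs), the large polyploid cells of the mouse placenta that face maternal tissue, and megakaryocytes (MKs), the polyploid bone marrow cells that release platelets, both multiply their genome without dividing. The arrays asked whether every part of the genome takes an equal share in this. TGCs were dissected by hand at embryonic day 9.5 from 29 implantation sites (replicate 1) and 14 implantation sites (replicate 2) of C57BL/6J mice. Their DNA was compared with that of embryonic cells of the same collection. MKs were grown for 4 days with thrombopoietin, the hormone of platelet formation, at 25 ng/ml from the marrow of 24 mice aged 6 to 8 weeks, and 1 array compared polyploid (16C-128C) MKs with diploid MKs. C is the DNA content of 1 haploid genome.

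The arrays differed in signal. Median Cy3 and Cy5 signals were 10.9 and 10.8 times those of the negative control spots on TGC replicate 1, 1.67 and 1.55 times on TGC replicate 2, and 1.13 and 2.23 times on the MK array. Probes well above background in both channels made up 93.4%, 62.4% and 26.0%, and the noise between neighbouring probes was 0.22, 0.43 and 0.69 on the log2 scale. The direction of MK ratios is unsettled: by the labels Cy5 holds the polyploid DNA, but the authors' smoothed MK values ran opposite to the Cy5 over Cy3 ratios (r = -0.785 over autosomal bins). Against MK ratios of mean minus local background signals r was 0.0763, and -0.829 after intensity loess of these. MK signs follow the labels throughout. Bin ratios correlated with probe GC content at r = -0.459 on TGC replicate 1, -0.0368 on TGC replicate 2 and -0.128 on the MK array (across bins, which are not independent). The number of arrays, 2 for TGCs and 1 for MKs, limits the precision. Each array was scanned on its own, so the scan and the MK cell type cannot be told apart.

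Stretches that were gene-poor on average were lower in TGCs than in embryonic cells, 60 of the 80 shorter than 1 Mb, and 52 held a named gene or transcript. The longest lay on chromosome 14 from 91000001 to 98200000 (7200 kb), with Pcdh9, a protocadherin of cell contacts, and Klhl1, a kelch-like protein of neurons. Its mean log2 ratio was -0.33 ± 0.02 (SD, n = 2), which is 0.795 times the embryonic level. The domain with the lowest mean, on chromosome 9 from 91100001 to 91400000, held Zic4 and Zic1, zinc finger transcription factors of the developing cerebellum, at -0.38 ± 0.04 (SD, n = 2). On chromosome 12 a domain from 96300001 to 97300000 with Flrt2, a membrane protein of axon guidance, stood at -0.35 ± 0.0016. Another from 95700001 to 96100000 without a named gene had -0.36 ± 0.10. On chromosome 8 the domain from 101500001 to 102100000 with Cdh8, a cadherin of neurons, had -0.32 ± 0.0065. Its neighbour from 101000001 to 101300000, without a named gene, had -0.32 ± 0.04. The arrays lay further apart in the short domains on chromosome 4 from 38000001 to 38200000 (-0.34 ± 0.30), on chromosome 1 from 114900001 to 115100000 (-0.33 ± 0.24) and on chromosome 13 from 88300001 to 88500000 (-0.32 ± 0.22). A further domain on chromosome 1 from 114100001 to 114400000 had -0.32 ± 0.13. In all, 654 of 23030 autosomal bins (2.84%) were called lower by limma, and 0 of 1389 bins of chromosome X. Of these, 521 formed 80 domains and 133 lay outside any. The domains lay on 17 chromosomes with a total length of 62.4 Mb, a median length of 400 kb and a mean of -0.26. Chromosome 14 held 16.2 Mb of them in 7 domains and chromosome 1 held 9.2 Mb in 13. All 80 were below 0 on both arrays, and 38 reached -0.2 on both. The domains were called on the mean of these same arrays, so a shared sign largely follows from that choice. In a comparison added after the domains were seen, their bins held 1.22 protein-coding genes per Mb against 7.22 over all autosomal bins (1-sided permutation p = 0.0013, circular shifts). They had a probe GC content of 36.2% against 36.7% (1-sided permutation p = 6e-04). Some domains were gene-dense. That on chromosome 10 from 80100001 to 80400000 held 23 named genes or transcripts, at -0.24 on TGC replicate 1 and -0.11 on TGC replicate 2. That on chromosome 4 from 154200001 to 154400000 held 11, at -0.26 and -0.17.

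Normexp background correction and the authors' smoothed values each gave lower domains that overlapped 43 of these 80. Filtering on probes bright on both TGC arrays gave 36, bins of 50 kb 38, bins of 500 kb 46, and probes bright on all 3 arrays, which left 9911 bins, 1. By size alone, 200 lower domains were counted without TGC replicate 1 and 199 without TGC replicate 2. Bins of both directions came to 3737 and 3370 by size alone against 2184 called with both arrays.

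**Figure D1:**
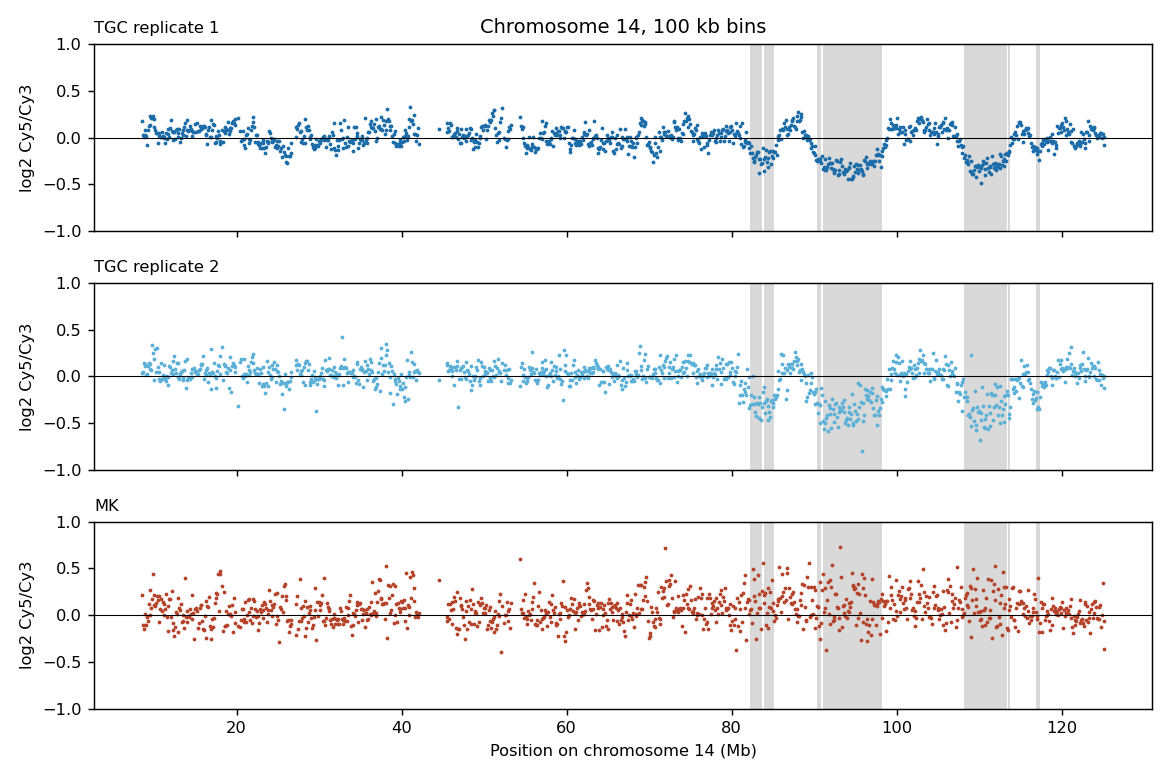
Log2 ratio of Cy5 over Cy3 (polyploid over diploid) in 100 kb bins along chromosome 14 (position in Mb) on TGC replicate 1, TGC replicate 2 and the MK array, with grey bands for the domains called lower in TGCs. The domain from 91000001 to 98200000 averaged -0.31 and -0.35 on the TGC arrays and 0.08 on the MK array.

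Regions chosen on 1 TGC array by size were lower on the other as well. The 113 lower autosomal regions of TGC replicate 1 averaged -0.14 on TGC replicate 2, with 106 below 0. The 120 of TGC replicate 2 averaged -0.19 on TGC replicate 1, with 116 below 0 (1-sided permutation p = 1e-04 each way, the smallest that 10000 circular shifts can give). The 138 higher autosomal regions of TGC replicate 1 averaged 0.13 on TGC replicate 2, with 136 above 0. The 25 of TGC replicate 2 averaged 0.21 on TGC replicate 1, with all 25 above 0 (permutation p = 1e-04 each way, again the smallest possible). Over 23030 autosomal bins the TGC arrays correlated at r = 0.478 (rho = 0.454, permutation p = 1e-04 for both, the smallest that the shifts can give), and at r = 0.333 after the called bins were left out. TGC replicate 1 and MK correlated at r = 0.0966 (rho = 0.122, permutation p = 5e-04 and 4e-04), and TGC replicate 2 and MK at r = -0.0151 (rho = 0.00994, permutation p = 0.18 and 0.32). Adjusted over the 3 pairs, the p for r was 3e-04, 0.00075 and 0.18. Bins are not independent replicates.

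**Figure D2:**
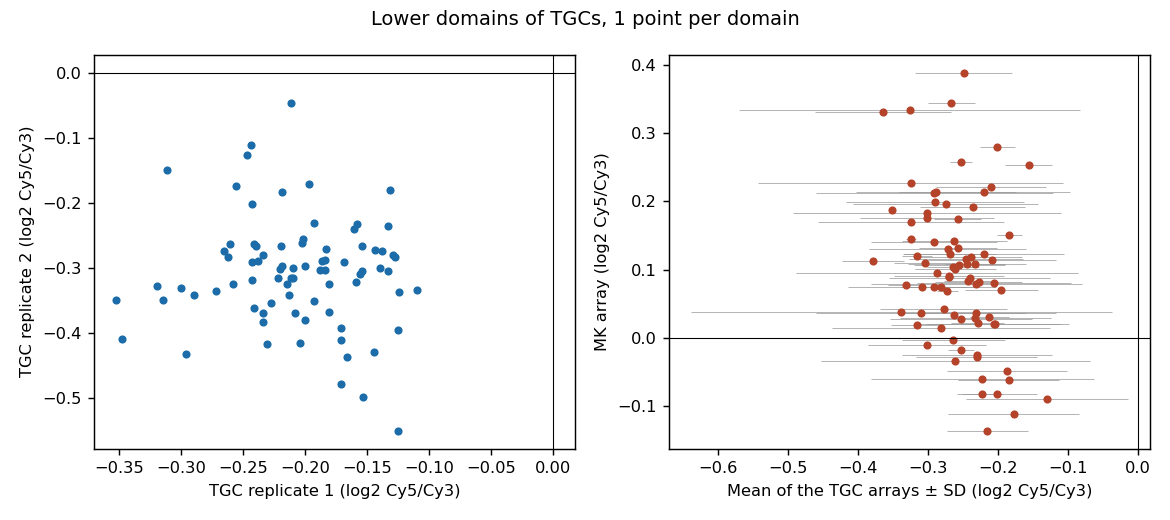
Each point is 1 of the 80 domains called lower in TGCs: mean log2 ratio on TGC replicate 1 against TGC replicate 2 (left), and TGC mean with SD (n = 2) against the MK array (right). All 80 were below 0 on both TGC arrays, on whose mean they had been called. On the MK array 14 were below 0, or 66 with its unsettled sign turned.

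Segments higher in TGCs had a median length of 300 kb on the autosomes and 850 kb on chromosome X. Chromosome X as a whole stood at 0.22 (mean of its medians on the TGC arrays). Its domains were therefore largely a shift of the whole chromosome cut at the threshold of 0.2. Among the autosomal ones, the domain on chromosome 16 from 65800001 to 66000000 with Vgll3, a cofactor of TEAD transcription factors, had a mean log2 ratio of 0.33 ± 0.05 (SD, n = 2). The domain on chromosome 7 from 27100001 to 27300000 with Nlrp4a and Nlrp9c, NLR family genes expressed in oocytes, had 0.33 ± 0.08. Domains on chromosome 3 from 15000001 to 15200000 (0.33 ± 0.06), chromosome 1 from 96100001 to 96300000 (0.32 ± 0.02) and chromosome 6 from 9200001 to 9400000 (0.31 ± 0.11) held transcripts without a gene symbol or none. The largest mean of all was on chromosome X from 60500001 to 62000000, with Slitrk4, a neuronal membrane protein, at 0.38 ± 0.09. Other domains of chromosome X ran from 124700001 to 128200000 with Diaph2, a formin (0.35 ± 0.08), and from 20400001 to 23600000 with Klhl13, a ubiquitin ligase adaptor, Wdr44 and Syn1, the synaptic vesicle protein synapsin (0.31 ± 0.06). Those from 124300001 to 124500000 (0.36 ± 0.16) and from 14200001 to 14500000 (0.33 ± 0.20) turned to -0.09 and -0.019 on probes bright on all 3 arrays. By limma, 673 autosomal bins (2.92%) and 857 of chromosome X (61.7%) were called higher. Of these, 331 formed 121 autosomal domains (38.9 Mb, 0.23 on average) and 829 formed 68 on chromosome X (95.2 Mb, 0.27 on average), while 342 autosomal ones and 28 of chromosome X lay outside any domain. Of the 121 autosomal domains, 7 were overlapped by a higher domain after normexp, 2 with the authors' smoothed values, 24 after a GC fit on bins, 30 on probes bright on both TGC arrays and 3 on probes bright on all 3 arrays. The overlap was 71 with bins of 50 kb, 15 with bins of 500 kb, 50 with the median of probes and 52 after loess. Counted by size alone, higher domains came to 264 without TGC replicate 1 and 403 without TGC replicate 2.

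**Figure D3:**
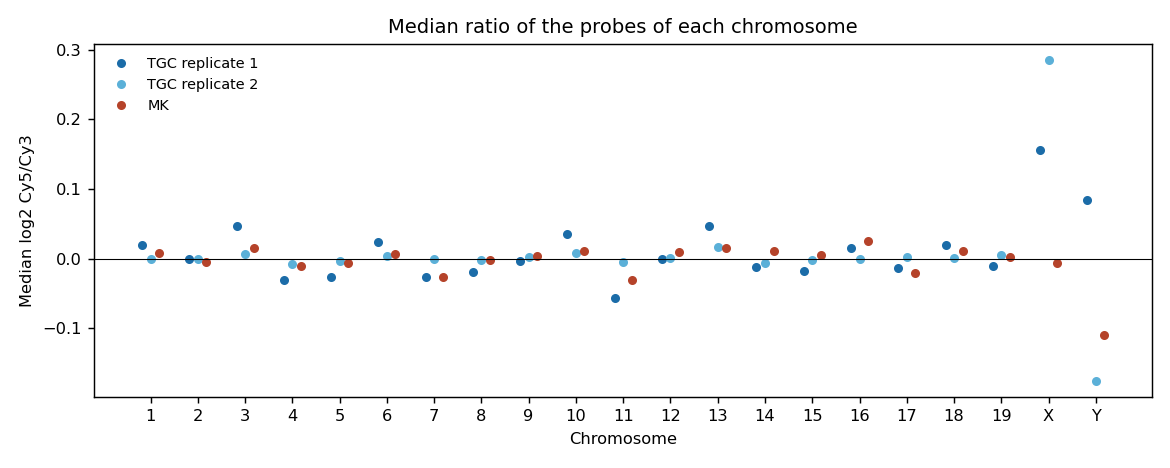
Median log2 ratio of Cy5 over Cy3 of the probes of each chromosome on the 3 arrays. Chromosome X stood at 0.16 and 0.28 on the TGC arrays and at -0.0062 on the MK array.

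Chromosome X as a whole was higher in TGCs than in embryonic cells on both arrays, and chromosome Y was not alike on them. The median of chromosome X probes was 0.16 on TGC replicate 1 and 0.28 on TGC replicate 2, a mean of 0.22 ± 0.09 (SD, n = 2) or 1.17 times the autosomal level, and -0.0062 on the MK array. No autosome had a TGC mean beyond the 0.03 of chromosome 13 and the -0.03 of chromosome 11. Chromosome Y, measured by 492 probes, had 0.08 on TGC replicate 1, -0.18 on TGC replicate 2 and -0.11 on the MK array. TGCs and embryos of 1 collection would have the same mix of sexes if each conceptus gave both alike, which was not tested, whereas maternal cells carry no Y. No test was made across 2 arrays; the mean for chromosome X was 0.10 after normexp, 0.12 on probes bright on all 3 arrays and 0.09 with the authors' smoothed values.

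Zic4 and Slitrk5 were the lowest genes in TGCs. Zic4 had a log2 ratio of -0.56 ± 0.09 (SD, n = 2; limma adjusted p = 1.7e-06) and Slitrk5, a synaptic membrane protein in the lower domain of chromosome 14 that starts at 108100001, -0.55 ± 0.06 (limma adjusted p = 0.0013). Sox10, a neural crest transcription factor, had -0.40 ± 0.12 and Foxa3, a transcription factor of liver, -0.41 ± 0.10. Adcyap1, the neuropeptide PACAP, had -0.43 ± 0.07 and Ndrg4 -0.40 ± 0.28. The kinase gene Map4k2 had -0.41 ± 0.02 and Trim65, a ubiquitin ligase, -0.43 ± 0.26. None of these 6 lay in a called domain. The transcripts AK133038 (-0.52 ± 0.31) and AK145334 (-0.43 ± 0.27) lay in lower domains of chromosomes 16 and 11. Highest was Ms4a6b, a membrane gene of immune cells, at 0.72 ± 0.07 (limma adjusted p = 1.1e-06), followed by the chromosome X transcripts AK085715 (0.59 ± 0.14) and ENSMUST00000087501 (0.58 ± 0.27). Serpinb1a, an inhibitor of neutrophil proteases, had 0.49 ± 0.22, and Cox7b, a subunit of cytochrome c oxidase on chromosome X, 0.49 ± 0.41. The zinc finger gene Zfp677 had 0.49 ± 0.24, the olfactory receptor gene Olfr741 0.49 ± 0.22 and Ermn, a cytoskeletal gene of oligodendrocytes, 0.49 ± 0.23. Gm4907 on chromosome X had 0.50 ± 0.16 and ENSMUST00000120266 on chromosome 13 0.52 ± 0.26. The adjusted p of these 20 genes went up to 0.044 and each rested on 5 to 13 probes; the test took its error from the probe number through the prior and not from the spread of the single gene. Of 16765 genes, 95 were called lower, 50 of them in a lower domain, and 530 higher, 268 of them among the 614 genes of chromosome X. That chromosome as a whole stood at 0.22. Without the trend in the prior variance 1 gene was called, higher, and with normexp 13 were called, all lower, Zic4 alone among these 20. By size alone, 3105 genes were counted without TGC replicate 1 and 3371 without TGC replicate 2; autosomal genes alone gave 78 lower and 234 higher.

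Placental and immune gene clusters were higher in TGCs. The prolactin family cluster on chromosome 13 from 27150677 to 28243104, which encodes hormones of trophoblast, had a log2 ratio of 0.25 ± 0.11 (SD, n = 2), with 8 of its 11 bins called higher. In its list, all 9 measured genes were above 0 on average, and Prl7b1 (0.45 ± 0.28) was called. Adjusted over the list alone 4 were called, with Prl7a1 (0.37 ± 0.10), Prl3a1 (0.34 ± 0.05) and Prl7a2 (0.32 ± 0.22). The placental cathepsin cluster on chromosome 13 from 60900828 to 61671165, proteases of trophoblast, had 0.19 ± 0.11 with 4 of 8 bins called higher. Its 2 measured genes Cts8 (0.19 ± 0.37) and Cts6 (0.08 ± 0.24) were too few for a test. The Serpinb genes, inhibitors of intracellular proteases, stood at 0.22 ± 0.03 in the cluster on chromosome 13 from 32935875 to 34093890, with 5 of 8 bins called higher. In that on chromosome 1 from 108758378 to 109504236 they stood at 0.14 ± 0.06, with 0 of 7 bins called, at percentile 94.6 of windows of the same length. All 20 measured Serpinb genes were above 0 on average, and 1 (Serpinb1a) was called. Adjusted over the list alone 4 were called, among them Serpinb9 (0.33 ± 0.09) and Serpinb2 (0.32 ± 0.13), and Serpinb9b had 0.29 ± 0.34. The NK receptor complex on chromosome 6 from 128559399 to 131196469, which encodes lectin-like receptors of natural killer cells, had 0.17 ± 0.05 with 5 of 17 bins called higher. Of 33 genes of that list, 29 were above 0, 4 were called and 5 were called adjusted over the list alone. The 4 were Clec4b2 (0.41 ± 0.29), Klrk1 (0.39 ± 0.12), Clec4a3 (0.36 ± 0.23) and Klra1 (0.33 ± 0.04), of which the 2 Clec genes lie outside the region above, and Klra5 had 0.35 ± 0.21. By camera the lists had an adjusted p = 9.2e-07 (prolactins), 1.7e-08 (Serpinb) and 1.8e-08 (NK complex), but adjusted p = 0.71, 0.63 and 0.63 with an estimated correlation. That correlation was 1 for prolactins, but -0.053 for Serpinb and -0.0076 for the NK complex, both below the preset 0.01. For the latter 2 lists the call was thus lost to the few degrees of freedom and not to the estimated correlation. With 1 residual degree of freedom that estimate is itself unsure, so correlation between neighbouring genes is not excluded. The median of each of these lists was at percentile 100 of 10000 random lists. Random lists were drawn over the whole genome, while genes of a cluster lie side by side and may share 1 regional value. The rank and the camera p at the preset correlation may therefore overstate the evidence.

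Sensory receptor families, which have no known part in placenta, were higher as well. Vomeronasal receptor genes, which detect pheromones, had a median of 0.17, with 47 of 51 above 0, 6 called and 7 called adjusted over the list alone. The 6 were Vmn2r79 (0.39 ± 0.11), Vmn2r16 (0.36 ± 0.13), Vmn2r108 (0.33 ± 0.02), Vmn2r105 (0.31 ± 0.02), Vmn2r19 (0.28 ± 0.01) and Vmn2r60 (0.28 ± 0.05), and Vmn2r81 had 0.32 ± 0.09. Olfactory receptor genes had a median of 0.11, with 13 of 16 above 0 and Olfr741 called, also adjusted over the list alone. Olfr75-ps1 had 0.29 ± 0.25, Olfr722 0.28 ± 2.6e-05 and Olfr44 0.28 ± 0.03. Their adjusted p was 4.6e-09 and 0.0022, but adjusted p = 0.71 and 0.67 with an estimated correlation. On probes bright on all 3 arrays the NK complex kept 3 of 33 genes and the vomeronasal receptors 8 of 51, and both list calls were lost (adjusted p = 0.067 each, medians 0.07 and 0.06). Prolactins and Serpinb genes kept 0 and olfactory receptors 1 there and were not tested. The vomeronasal median was 0.11 after normexp and 0.07 with the authors' smoothed values, and 0.24 and 0.11 on the single arrays.

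The Psg and Ceacam cluster, pregnancy-specific and related adhesion glycoproteins on chromosome 7 from 17234791 to 19406055, had 0.03 ± 0.03 as a whole and -0.0049 on probes bright on all 3 arrays. Within it, 5 of 17 bins were called higher, all in the domain from 18200001 to 18800000 (0.24 ± 0.01). The 14 measured genes of the family list, some of which lie outside the cluster, had a median of -0.04 but a mean of 0.05, and none was called. Ceacam11 (0.37 ± 0.18), Psg25 (0.29 ± 0.30), Ceacam5 (0.25 ± 0.07) and Ceacam2 (-0.20 ± 0.07) had the largest values. Camera put the list up at an adjusted p = 0.61, and adjusted p = 0.79 with an estimated correlation. The median turned positive after normexp (0.03), loess and a GC fit on probes and with the authors' smoothed values (0.02), which alone called the list (adjusted p = 0.0029).

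**Figure D4:**
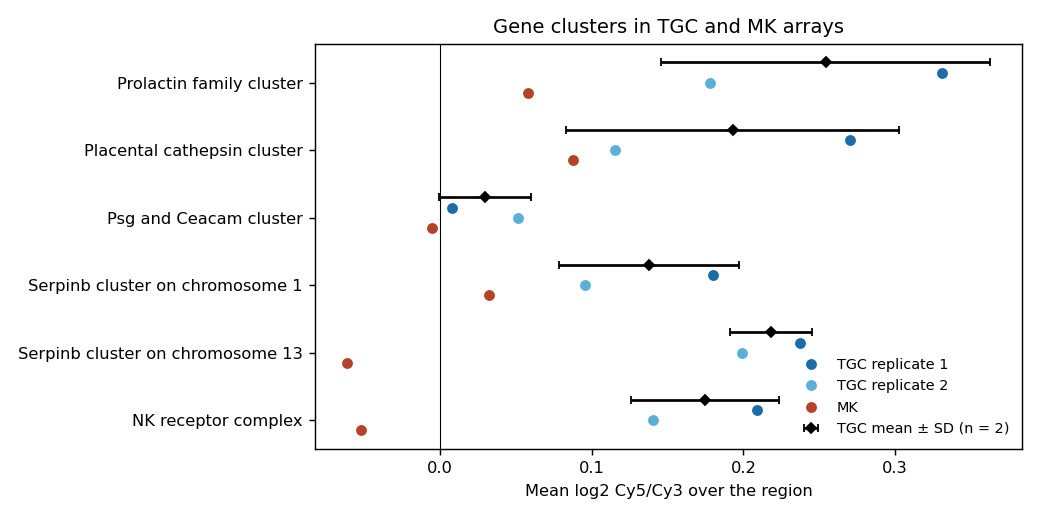
Mean log2 ratio of Cy5 over Cy3 over each gene cluster on TGC replicate 1, TGC replicate 2 and the MK array, with the TGC mean and SD (n = 2) as diamonds and bars. The prolactin cluster stood at 0.33 and 0.18 on the TGC arrays and at 0.06 on the MK array.

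Very long genes of neurons and cell adhesion, and cadherins and protocadherins, were lower in TGCs as lists by a small median. The camera adjusted p was 0.014 for the long genes (median -0.03) and 0.0022 for the cadherins (median -0.07), but adjusted p = 0.71 and 0.67 with an estimated correlation. Pcdh9 had -0.38 ± 0.02 (SD, n = 2), Ptprd, a receptor phosphatase of synapses, -0.27 ± 0.02. Robo1 and Robo2, receptors of axon guidance, had -0.27 ± 0.0067 and -0.23 ± 0.02 and Csmd3 -0.20 ± 0.06, and these 5 were called lower. Dmd, the dystrophin gene on chromosome X, was called higher at 0.21 ± 0.07, near the 0.22 of that chromosome as a whole. The list held 42 genes, of which 13 were above 0, and the same 6 genes were called adjusted over the list alone. Among 35 cadherins and protocadherins Pcdh9, Cdh19 (-0.34 ± 0.16), Cdh8 (-0.32 ± 0.0052), Cdh15 (-0.29 ± 0.02) and Cdh7 (-0.25 ± 0.0023) were called lower. Pcdh19 on chromosome X (0.24 ± 0.03), again near the level of that chromosome, was called higher, and the same 6 were called adjusted over the list alone. The call of the long genes was lost on probes bright on all 3 arrays (adjusted p = 0.067), where all 42 were still measured and the median was again -0.03.

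Genes of the trophoblast lineage, of megakaryocytes, of the endocycle and of housekeeping complexes did not stand apart as lists in TGCs. Among 21 trophoblast genes Hsd3b6, an enzyme of steroid synthesis, was called higher (0.43 ± 0.22), also adjusted over the list alone. Cyp11a1, which starts steroid synthesis, had -0.20 ± 0.05, Plac1 0.19 ± 0.09 and the imprinted gene Peg10 -0.17 ± 0.20 (list adjusted p = 0.20, and adjusted p = 0.79 with an estimated correlation). None of 19 megakaryocyte genes was called, with Nfe2 at -0.22 ± 0.03, Gata1 at 0.22 ± 0.20, Zfpm1 at -0.19 ± 0.16 and Thbs1 at -0.16 ± 0.0015 (adjusted p = 0.28, and adjusted p = 0.79 with an estimated correlation). None of 30 endocycle regulators was called either, with the replication helicase gene Mcm7 at -0.35 ± 0.07, the cyclins Ccnd1 at -0.26 ± 0.13 and Ccnd2 at -0.20 ± 0.0047 and the inhibitor Cdkn1a at -0.25 ± 0.17 (adjusted p = 0.13, and adjusted p = 0.79 with an estimated correlation; called down at 0.026 after normexp). Of 28 proteasome genes Psmd1 was called higher (0.23 ± 0.06), also adjusted over the list alone. Psmd6 had 0.23 ± 0.0063, Psma2 0.22 ± 0.21 and Psmd9 -0.20 ± 0.10 (adjusted p = 0.37, and adjusted p = 0.79 with an estimated correlation; called up at 0.015 on probes bright on all 3 arrays). The 3 measured ribosomal protein genes Rps15a, Rpl22 and Rpl3l had 0.11 ± 0.09, -0.05 ± 0.21 and -0.01 ± 0.28 (adjusted p = 0.96, and adjusted p = 0.98 with an estimated correlation). The 2 histone cluster genes H2bc4 and H2bc6 had 0.15 ± 0.01 and 0.11 ± 0.10.

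On the MK array, higher stretches were short, and the highest held no gene symbol. The signs follow the labels and are unsettled, since the authors' smoothed MK values run the other way. The largest regions lay on chromosome 9 from 91700001 to 92000000 (0.51), on chromosome 7 from 79700001 to 80000000 (0.51) and from 84400001 to 84700000 (0.51). They were followed by chromosome 12 from 65100001 to 65500000 (0.50) and chromosome 2 from 82300001 to 82600000 (0.49). The lowest were on chromosome 7 from 26700001 to 27100000 with Cyp2b13 and Cyp2b9, cytochromes of drug metabolism (-0.31). On chromosome 5 the region from 87500001 to 87800000 with Ugt2b36, Ugt2b5 and Ugt2a3, enzymes of glucuronidation, had -0.26. On chromosome X the lowest were those from 76900001 to 77200000 with Mageb16 (-0.28), from 116900001 to 117200000 with Pabpc5 (-0.27) and from 80700001 to 81000000 within Dmd (-0.26). By size alone, 316 regions were higher and 8 lower on the MK array, against 191 higher and 113 lower on TGC replicate 1 and 126 higher and 122 lower on TGC replicate 2. Of the higher ones, 307 (MK), 138 (TGC replicate 1) and 25 (TGC replicate 2) lay on autosomes. With the MK sign turned, 8 MK regions were higher and 316 lower. Probes were centred by their median but bins are means, and autosomal bins averaged 0.065 on the MK array. On the TGC arrays they averaged 0.017 and 0.019. This offset tilts the fixed threshold towards higher MK regions, or towards lower ones with the sign turned. The longest higher region measured 1100 kb on the MK array, 2500 kb on TGC replicate 1 and 6100 kb on TGC replicate 2. The longest lower region measured 400, 7200 and 3600 kb in the same order. The MK count was 0 with the authors' smoothed values, 2 on probes bright on all 3 arrays, 6 on probes bright on the MK array, 103 after loess, 641 centred on the mode, and 115 lower beside 25 higher after normexp. No region was tested, since there was 1 array.

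Vomeronasal receptor genes had a median of -0.15 on the MK array, at percentile 0.04 of random lists, and the very long neuronal genes 0.07, at percentile 97.8. With the MK sign turned these were 0.15 at percentile 99.97 and -0.07 at percentile 2.01. The other 13 measured lists lay between percentiles 8.77 and 97.1, with megakaryocyte genes at a median of -0.05 and endocycle regulators at 0.08. With the sign turned they lay between percentiles 3.35 and 91.0, with medians of 0.05 and -0.08 for these 2. After normexp 4 lists were outside the middle 95% of random lists, and on probes bright on all 3 arrays 0. The immunoglobulin and T cell receptor loci, which lose DNA in lymphocytes, had no gene with enough probes. As regions on the MK array they had -0.0048 (heavy chain, chromosome 12), -0.03 (kappa, chromosome 6), 0.05 (alpha and delta, chromosome 14) and 0.02 (beta, chromosome 6), against 0.12 ± 0.06, 0.09 ± 0.06, 0.06 ± 0.03 and 0.11 ± 0.09 (SD, n = 2) in TGCs.

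The difference between TGCs and MKs in the lower TGC domains hung on the MK sign in most of the named ones. It was -0.49 in the domain of Zic4 and Zic1, -0.54 in that of Flrt2, -0.41 in that of Pcdh9 and Klhl1 and -0.47 in that of Cdh8, but -0.27, -0.16, -0.26 and -0.18 with the MK sign turned. Other named domains had -0.38 on chromosome 4 from 38000001 (0 of 2 bins called), -0.33 on chromosome 8 from 101000001 (1 of 3) and -0.55 on chromosome 13 from 88300001 (1 of 2). With the sign turned the first 2 of these were little changed at -0.30 each, and the last had -0.10. In the lower TGC domains, 330 of 623 tested bins had a difference called lower, and in 33 of the 80 domains more than 50% of bins did. With the sign turned these were 126 bins and 2 domains. The domains had been chosen for low TGC values, so a part of the difference follows from that choice. The MK array was noisier than the test assumes, with an autosomal bin SD of 0.161 against 0.128 and 0.130. Over the genome, limma called 1315 bins lower and 748 higher in TGCs minus MKs, 317 of the latter on chromosome X. With the MK sign turned the counts were 451 lower and 3143 higher, 602 of the latter on chromosome X, and with the authors' smoothed values 1 bin was called. Autosomal bins averaged 0.065 on the MK array against 0.017 and 0.019 on the TGC arrays. That offset tilts the difference towards lower, and towards higher with the sign turned. By size alone 7436 bins differed without TGC replicate 1 and 7102 without TGC replicate 2.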

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

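The tests of dye bias, of similar sequences in gene families and of maternal cells were chosen after the results were seen, and the GC fit on bins and the filter on dim probes were chosen after the data were seen but before their own values were known.

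A test of the difference in the polyploid over diploid ratio between TGCs and MKs assumed that the lone MK array varies like the TGC arrays, although its noise between neighbouring probes was 0.69 against 0.22 and 0.43. It called 1315 bins lower and 748 higher, 317 of them on chromosome X, but 451 lower and 3143 higher (602 on chromosome X) with the unsettled MK sign turned and 1 bin with the authors' smoothed values. The mean of autosomal bins was 0.065 on the MK array against 0.017 and 0.019 on the TGC arrays, which tilts these counts. In the named TGC domains with most bins called, which had been picked for low TGC values, the difference was -0.49 on chromosome 9 from 91100001 (Zic4, Zic1), -0.70 on chromosome 12 from 95700001 and -0.54 from 96300001 (Flrt2), -0.41 on chromosome 14 from 91000001 (Pcdh9, Klhl1), -0.66 on chromosome 1 from 114900001 and -0.49 from 114100001, and -0.47 on chromosome 8 from 101500001 (Cdh8). With the sign turned these were -0.27, -0.03, -0.16, -0.26, 0.0075, -0.15 and -0.18 in the same order, so a difference between the cell types in these domains stays open.

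The lower TGC domains averaged -0.26 over 80 domains. After a fit of bin values on probe GC the mean was -0.30 (SD over domains 0.07), and domains called anew overlapped 74 of the 80. The trend with probe GC thus does not account for the whole pattern. On probes well above background on both TGC arrays the mean was -0.23 (SD 0.06). The domains had been called low on these same arrays, which holds that mean down, and calling anew on these probes overlapped 36 of the 80. A part played by dim probes therefore stays open. Dye bias would lower the red over green ratio of the same probes on any array. The MK array averaged 0.10 there (SD 0.11), against 0.07 over all autosomal bins. That is 1 dim array of unsettled direction without a dye swap, so dye bias and fewer copies in TGCs cannot be told apart. Fewer copies of these domains in TGCs than in embryonic cells, as incomplete replication would give, remains a hypothesis.

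The prolactin, cathepsin, Serpinb (chromosome 13) and NK receptor clusters were higher in TGCs, with a mean of 0.21. After the GC fit the mean was 0.16, so the trend with GC is not the whole cause. The 59 genes of these clusters lay 0.063 (SD between arrays 0.01) above 67 olfactory and vomeronasal receptor genes, 0.22 against 0.15, and that test had required more than 0.1 of a gain particular to these clusters. Similar sequences in tandem gene families, or another property that such families share, may therefore account for most of it. A gain of copies at placental genes was not tested apart from this.

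Chromosome X lay above autosomal bins of the same GC by 0.13 on TGC replicate 1 and 0.28 on TGC replicate 2, so GC content is not its whole cause. Maternal cells in the TGC fraction, or more female tissue than in the embryonic sample, would raise X and lower Y. The Y values needed below assume equal numbers of male and female conceptuses and Y probes that follow Y copies in full. Neither was tested, and the intervals measure the scatter of probes within 1 array. On bright probes, X of TGC replicate 1 (0.13) would need Y at -0.47. Y was at -0.016 (95% bootstrap interval -0.047 to 0.029), which under these assumptions argues against maternal cells or another sex mix on that array. On TGC replicate 2, X (0.29) would need Y at -1.62, and Y was at -0.24 (-0.32 to -0.14), below 0 but far from that, so maternal cells or another sex mix may account for a part and stay open on this array. An X chromosome with more copies in TGCs than in embryonic cells was not tested otherwise.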

How the results depend on the processing

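The GC fit on bins, the filters on probes bright on the TGC or the MK arrays, the turned MK sign, autosomal genes only and all repeats of the MK list ranks were chosen after the data were seen. The correlation between the TGC arrays stayed positive in all settings run (0.303 to 0.642), as did chromosome X. Of the values of 20 named genes under other settings, 175 kept direction and call and 55 kept direction but lost the call. Of those of the named domains 210 moved by less than the spread between arrays, 68 moved further and 2 reversed.

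Bins of 50 kb gave 411 TGC domains and 144 MK regions. Bins of 500 kb, which are fewer by construction, gave 397 TGC bins, 57 TGC domains, 12 MK regions and 429 bins of TGC minus MK. Medians of probes gave 3592 bins of TGC minus MK. At least 20 probes per bin and 10 per gene, which leaves fewer of both, gave 1308 TGC bins, 38 MK regions, 915 bins of TGC minus MK and 1 MK list. Normexp gave 477 TGC bins (383 lower, 94 higher), 77 TGC domains, 13 genes, 140 MK regions, 4 MK lists and an X mean of 0.097. Loess gave 103 MK regions, centring on the mode 641 and the GC fit on probes 1 MK list. Probes bright on all 3 arrays, far fewer, gave 76 TGC bins, 6 TGC domains, 153 genes, 2 TGC lists, 0 MK lists, 2 MK regions, 1127 bins of TGC minus MK and an X mean of 0.12; there the domains of chromosome X from 14200001 and 124300001 reversed to -0.019 and -0.092 and the Psg and Ceacam cluster to -0.0049. A size of 0.1 gave 431 TGC domains and 1046 MK regions, and 0.3 gave 630 TGC bins, 113 TGC domains, 255 genes and 62 MK regions, by construction. Without the variance trend 1 gene was called. The authors' smoothed values gave 485 TGC bins (437 lower, 48 higher), 61 TGC domains, 42 genes, 0 MK regions, 1 bin of TGC minus MK and an X mean of 0.094. An estimated correlation called 0 lists, but with 2 arrays that test could hardly call any. MK runs of 2 bins gave 907 regions and of 5 bins 41.

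Leaving out either TGC array, which leaves size alone, gave 3370 to 3737 TGC bins, 464 to 602 TGC domains, 3105 to 3371 genes and 7102 to 7436 bins of TGC minus MK. The GC fit on bins gave 3559 bins of TGC minus MK and the turned MK sign 3594. Probes bright on both TGC arrays gave 1133 TGC bins, those bright on the MK array 6 MK regions, and autosomal genes alone 312 genes. Of called TGC bins 70.1% were higher, but 45.5% after loess (1015 lower, 848 higher) and 46.1% after the GC fit on bins (1007 lower, 861 higher). Beyond what construction shows, the cause was not tested. No paired analysis of TGCs and MKs was possible because nothing in the labels links a TGC array to the MK array. Signal over background limits most the MK array, where 26.0% of probes were well above background in both channels, and then TGC replicate 2 (62.4%).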

Other observations

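The context of the domains, the comparison with the authors' smoothed values and the MK ratio in the lower domains were looked at after the domains were seen; the tests of region length and profile were chosen before their results were seen, but reading the profile against its spread was decided after its values were seen.

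Some genes of the longer lower domains beside those already named were picked out here after their values were seen. Brinp3 (-0.29 ± 0.04, model SE, which is set by the probe number; limma adjusted p = 2.7e-08) and Ncam2, a neural adhesion molecule (-0.25 ± 0.04; limma adjusted p = 1.8e-06), were called lower, whereas Pcdh7 (-0.19 ± 0.04), Pcdh17 (-0.15 ± 0.06) and Slitrk6 (-0.28 ± 0.14) were not. Of the 80 lower domains 52 held a named gene or transcript, and of the 189 higher ones 169. Bins of higher autosomal domains had 5.92 protein-coding genes per Mb against 7.22 over all autosomal bins (1-sided permutation p = 0.098) and a probe GC content of 36.1% against 36.7% (1-sided permutation p = 1e-04, the smallest that the shifts can give).

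The authors' smoothed values correlated with the log2 ratios at r = 0.960 on TGC replicate 1, 0.683 on TGC replicate 2 and -0.785 on the MK array, across autosomal bins. Against ratios of mean minus local background signals r was 0.953, 0.890 and 0.0763, and after intensity loess of these 0.941, 0.767 and -0.829. On the MK array the ratio in the bins of the lower TGC domains was 0.10 against 0.07 over all autosomal bins (1-sided permutation p = 0.003 on the high side). With the MK sign turned these were -0.10 against -0.07, and the same p is on the low side. The result depended on which TGC array defined the regions. Bins of the 113 lower regions found on TGC replicate 1 had 0.03 on the MK array (1-sided permutation p = 5e-04 on the low side), and those of the 120 found on TGC replicate 2 had 0.12. Whether the lower regions of TGCs are lower in MKs stays open.

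Whether longer lower regions are more deeply reduced was tested on regions found on 1 TGC array and measured on the other. The rank correlation of length with the value was -0.174 for 113 regions of TGC replicate 1 measured on TGC replicate 2 (permutation p = 0.065) and -0.399 for 120 regions the other way (permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted over both 0.065 and 2e-05). Regions of at least 10 bins averaged -0.24 (SD 0.13, 10 regions) against -0.13 (SD 0.13, 82 regions) in those of at most 5 bins on TGC replicate 2, and -0.25 against -0.17 on TGC replicate 1. The relation passed 1 way only. Moreover, a short run found on 1 array is more easily noise, which moves its value on the other array towards 0. The test cannot tell this from deeper loss in longer regions, so the relation stays open. Whether the loss is graded from edge to centre was tested in regions of at least 5 bins, where middle minus outer bins came to 0.0026 (SD 0.04, 45 regions, permutation p = 0.68) on TGC replicate 1 and 0.0024 (SD 0.08, 41 regions, permutation p = 0.85) on TGC replicate 2. Both lay above 0, which by the bound set before the test spoke against deeper loss at the centre. They did so by less than their spread over regions, so no grading within regions was detected and a small one was not excluded. Bins next to the regions were at -0.20 on TGC replicate 1 and -0.095 on TGC replicate 2, against -0.23 and -0.16 in the outer bins. The size rule may thus have cut inside lower stretches, so the test cannot decide on grading beyond its limits.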
